A study of Homo sapiens with 9 samples.

How the data were processed

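RNA sequencing values were deposited for 9 libraries of PANC-1 cells, an established line from a human pancreatic carcinoma. The labels give 3 groups, namely control, siSIRT6 and siKDM5C, with 3 replicates each, taken 48 hours after transfection with short interfering RNAs (siRNAs). The column headers name the control libraries siNC, a usual abbreviation for a negative control siRNA. The labels describe total RNA extracted with Trizol and a stranded mRNA library kit. The sequences and the number of the siRNAs are not given in the sources used here. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between samples that may be technical replicates.

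Per the labels, the authors' processing used Trimmomatic, HISAT2, Cufflinks, HTSeq and the hg38 genome build, without versions and without the part each tool played. The deposited files hold 1 FPKM value (fragments per kilobase of gene, scaled to the reads of the library) per library for each of 36753 Ensembl gene identifiers, made by the authors, with no pooling of replicates. The unit was read from the values: low values of a gene are whole multiples of 1 step per library, and the step depends on the gene's length and the library's depth. The annotation behind the values and the strand on which reads were counted are not given in the sources used here. Gene symbols came from a table of gene names, which held 36659 of the identifiers, and from GENCODE release 29 (GRCh38), which held 35564. There was no symbol for 8 identifiers. Coordinates are those of GENCODE release 29.

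Whole reads were recovered from the FPKM steps for 100% of the genes (tolerance 0.01 of a read), with the union of annotated exons as the length for 58.93% of genes and another whole length for the other 41.07%. The implied reads in genes were 18201413, 19072856 and 18664996 for control replicates 1, 2 and 3. They were 19674846, 19312544 and 26910441 for siSIRT6, and 19095613, 18499707 and 23270854 for siKDM5C. At these depths a gene of 1 kilobase with 0 reads could hold up to 0.112 FPKM in the deepest library and 0.165 FPKM in the shallowest (3 reads, counting error only). The recovered reads served for the expression minimum of named genes, for a check of replicate noise and for 1 alternative fit.

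The plan made before the data were examined named a count model for raw counts and, for files that hold FPKM, limma-trend on log2 values. Since the values are FPKM, the limma-trend plan was followed, and edgeR and DESeq2 were not run. The 16135 genes with at least 1 FPKM in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in a single fit of all 9 libraries with a term per group and empirical Bayes moderation with a trend (6 residual degrees of freedom before moderation). No further scaling between libraries was applied. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05 for each of 3 comparisons, which were siSIRT6 against control, siKDM5C against control, and siSIRT6 against siKDM5C. Fold changes are differences of log2(FPKM + 1) and are smaller than ratios of FPKM for genes with low values. Errors of FPKM are standard deviations (SD, n = 3).

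The 47 gene lists fixed before the data were examined covered signalling and stress pathways, metabolism, the cell cycle, chromatin enzymes, pancreatic cancer subtypes and markers of other cell types. The 38 lists with at least 5 tested members were tested with camera (limma) at a preset correlation between genes of 0.01, which asks whether a list moved relative to all other tested genes. Benjamini-Hochberg adjustment ran over the 38 lists. Counts of members that rose and fell are given over all genes tested and, beside them, adjusted over the list alone. Camera with a correlation estimated for each list and fry, which tests a list without comparison with other genes, were alternatives.

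Named genes followed a rule fixed before the data were examined. They were SIRT6 and KDM5C in every library; in each knockdown comparison the 10 highest rises and the 10 largest falls past the threshold with a mean CPM of at least 4 from the recovered reads, a gene symbol that is not a clone name, and all 3 knockdown libraries on 1 side of all 3 controls; up to 4 members with the smallest adjusted p per list; the 6 genes that moved most in both knockdowns in the same direction and the 6 in opposite directions; and the 5 largest differences each way between the knockdowns. Members named as exceptions to the direction of their list fell outside the rule and were chosen after their values were seen. Some single genes that met the rule are not reported.

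Genes changed the same way by both knockdowns were compared with the count for independent lists, and the covariance of the fold changes with 100 simulations of groups without any effect against the same 3 controls. Heptamers in annotated 3' UTRs (15508 heptamers, 10587 protein-coding genes with a mean CPM of at least 4 from the recovered reads) were tested for a shift of the fold changes, with the UTR's length and dinucleotide content taken into account, against 100 permutations. The fit and the list test, but not the heptamer or overlap steps, were run on simulated data made from the deposited values. With 200 changed genes in each of 10 runs, 52.4% of genes changed 1.5-fold, 80.1% of those changed 2-fold and 95.6% of those changed 4-fold were recovered. Of unchanged genes 0.06% were called. The simulated noise was independent between genes, and far fewer genes changed than in the deposited data, so these rates need not hold there.

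Alternatives changed the scaling between libraries, the pseudocount, the filter on low values, the libraries in the fit, the threshold, the empirical Bayes fit and the list test, added the replicate number as a block, and left out each library in turn. Those chosen after seeing the data were limma-voom on the recovered reads, protein-coding genes alone, genes outside the leading heptamer families, and removal of the trend on GC content and gene length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for gene tables, sequence counts and figures.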

Results

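The 9 libraries measured the transcripts of PANC-1 cells 48 hours after transfection, with 3 control, 3 siSIRT6 and 3 siKDM5C libraries. SIRT6 encodes a nuclear deacylase of histones and other proteins that uses NAD, and KDM5C encodes an X-linked demethylase of lysine 4 of histone H3. The FPKM steps implied 18201413 to 26910441 reads in genes per library, and siSIRT6 replicate 3 was the deepest. Across genes, Pearson's r of log2(FPKM + 1) between libraries of the same group was 0.980 to 0.991. It was 0.947 to 0.953 between control and siSIRT6, 0.943 to 0.953 between control and siKDM5C, and 0.961 to 0.965 between the knockdowns, so each knockdown lay nearer to the other than to the control. The first principal component, with 45.5% of the variance, separated the control from both knockdowns, and the second, with 27.8%, separated the knockdowns from each other. Transcripts of mitochondrial DNA took 8.72% ± 0.916 of the recovered reads in control, 6.73% ± 0.202 in siSIRT6 and 6.27% ± 0.546 in siKDM5C (SD, n = 3).

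The level of each target in each library came first. SIRT6 (ENSG00000077463, chromosome 19, 4174109 to 4182604, GRCh38) was at 6.2, 5.17 and 7.17 FPKM in control replicates 1, 2 and 3, at 0.795, 0.509 and 0.487 FPKM in siSIRT6, and at 5.05, 4.6 and 5.39 FPKM in siKDM5C. The siSIRT6 mean was 9.66% of the control mean, a fall of SIRT6 with a log2 fold change of -2.16 (SE 0.12, adjusted p = 2.92e-06). KDM5C (ENSG00000126012, chromosome X, 53191321 to 53225422) was at 18, 18.4 and 18.8 FPKM in control, at 17.9, 17.6 and 17.9 FPKM in siSIRT6, and at 3.65, 3.31 and 3.89 FPKM in siKDM5C. The siKDM5C mean was 19.6% of the control mean, with a log2 fold change of -2.07 (SE 0.05, adjusted p = 8e-08). KDM5C after siSIRT6 stood at 96.7% of control and did not pass the test (log2 fold change -0.05, adjusted p = 0.513), although with the GC and length trend removed it did (-0.15, adjusted p = 0.00567, range over alternatives 0.00567 to 0.945). SIRT6 after siKDM5C stood at 81.2% of control and did not pass (log2 fold change -0.25, adjusted p = 0.106), although without control replicate 2 it did (-0.35, adjusted p = 0.0337), as it did with the GC and length trend removed (-0.30, adjusted p = 0.0169), and without control replicate 3 the fold change was -0.15 (adjusted p = 0.308).

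**Figure D1:**
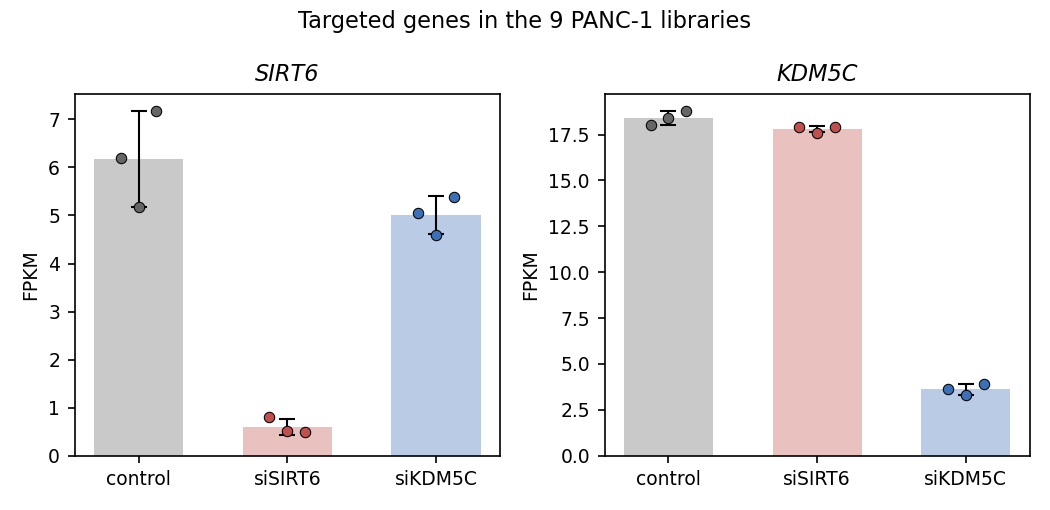
FPKM of SIRT6 and KDM5C in the control, siSIRT6 and siKDM5C groups, with bars at the mean of 3 libraries, points for the libraries and error bars of 1 SD. SIRT6 fell from a mean of 6.18 to 0.597 FPKM after siSIRT6, and KDM5C from 18.4 to 3.61 FPKM after siKDM5C.

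The comparison of siSIRT6 with control asked which transcripts of these cells change when SIRT6 is lowered. Genes of mitosis and DNA replication and the inflammatory genes driven by NF-kB fell, while mesenchymal and cholesterol synthesis genes rose. Values of histone genes, a quality list in the plan, rose too. All these calls came at the preset correlation between genes and none with an estimated one. PLK1, a kinase needed for entry into mitosis, went from 24.4 ± 1.43 to 8.30 ± 0.161 FPKM, and the proliferation marker MKI67 from 27.7 ± 0.445 to 11.8 ± 0.257 FPKM. ICAM1, an adhesion receptor for leukocytes, went from 633 ± 15 to 150 ± 1.87 FPKM. COL5A1, a fibrillar collagen, rose from 5.20 ± 0.219 to 24.5 ± 0.674 FPKM (SD, n = 3 throughout).

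Of the 16135 genes tested, 3861 rose and 4333 fell after siSIRT6, 8194 in all, with a median size of 0.45 on the log2 scale. Of those tested, 11494 were protein-coding and 1685 antisense genes, and 6428 of the 8194 were protein-coding. Antisense genes followed the coding genes they overlap, so some changes may be counted more than once, here and in later counts. At least 1 log2 was reached by 351 of the rises and 345 of the falls. The 3 siSIRT6 libraries lay entirely above or entirely below the 3 controls for 65.5% of genes, against 10% by chance. The balance of rises and falls depended on the scaling between libraries, since median-of-ratios scaling gave 4273 rises and 3893 falls.

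The highest rise was that of the carboxypeptidase gene CPA4 (ENSG00000128510, chromosome 7, 130293134 to 130324180), from 1.07 ± 0.254 to 28.4 ± 0.495 FPKM, a log2 fold change of 3.84 (SE 0.08, adjusted p = 9.12e-08). The opsin gene OPN3 rose from 3.81 ± 0.684 to 45.6 ± 0.415 FPKM and KMO, an enzyme gene of tryptophan breakdown, from 1.62 ± 0.249 to 20.8 ± 0.274 FPKM. OPN3 and KMO overlap on opposite strands, and the strand counted is not given in the sources used here, so part of either rise can belong to the other. The secreted netrin NTN4 rose from 11.8 ± 0.350 to 76.4 ± 0.347 FPKM, and the matrix protein gene THBS1 from 2.46 ± 0.173 to 16.9 ± 0.179 FPKM together with the antisense gene THBS1-AS1 inside it. KIF1C-AS1, PERP, B3GNT7 and SLITRK6 completed the 10 highest rises, with log2 fold changes from 2.14 for SLITRK6 to 2.37 for KIF1C-AS1. The largest fall was that of AMPD3 (ENSG00000133805, chromosome 11, 10308313 to 10507579), which encodes an AMP deaminase, from 23.3 ± 0.565 to 3.10 ± 0.227 FPKM (log2 fold change -2.57, SE 0.05, adjusted p = 9.12e-08). The lipid scramblase family gene ANO9 fell from 13.7 ± 1.72 to 1.57 ± 0.169 FPKM, cyclin gene CCND1 (ENSG00000110092, chromosome 11, 69641087 to 69654474) from 205 ± 15.5 to 48.7 ± 0.187 FPKM, and the paraspeckle RNA NEAT1 from 35.7 ± 3.84 to 8.65 ± 1.85 FPKM. The other large falls were SIRT6 itself, ICAM1 with its antisense neighbour ICAM4-AS1, the cytokine gene EBI3, the chemokine gene CCL20 and DAZAP2. The 3' UTRs of SIRT6, AMPD3, CCND1 and DAZAP2 hold the heptamer ACTTGTT, which is met more often in genes that fell after siSIRT6, and so do those of THBS1 and PERP, which rose.

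Of the 38 lists tested, 15 moved after siSIRT6 at the preset correlation, 6 up and 9 down, and 0 did with an estimated correlation, where the lowest adjusted p = 0.0512. The list of G2/M genes fell, with 29 of 33 members lower, 1 higher and 3 not passed (median log2 fold change -0.89, adjusted p = 2.25e-11), and had adjusted p = 0.0924 with an estimated correlation. PLK1, KIF2C, KIF23 and MKI67 led it, and the exception was CDC25B, which rose from 59.8 ± 1.15 to 87.8 ± 0.597 FPKM. Of 35 G1/S genes, 23 fell, 2 rose and 10 did not pass (median -0.35, adjusted p = 3.64e-05; adjusted p = 0.0512 with an estimated correlation). FEN1 fell from 25.3 ± 1.15 to 13.9 ± 0.429 FPKM and MCM2 from 18.6 ± 0.555 to 11.3 ± 0.487 FPKM, while CCNE1 and E2F1 rose. Double-strand break repair genes fell in 19 of 26 cases, with 2 rises and 5 not passed (median -0.35, adjusted p = 0.000721; adjusted p = 0.361 with an estimated correlation), led by PARP1 (10.9 ± 0.520 to 5.22 ± 0.0782 FPKM), FANCI, FANCD2 and RAD54L. Replication-dependent histone genes went the other way, with 10 of 16 up, 0 down and 6 not passed (median 0.51, adjusted p = 3.64e-05; adjusted p = 0.0512 with an estimated correlation). Of 37 such genes with deposited values, 16 were tested. The histone median depended on the filter on low values and was close to no change without a filter. The plan counted the histones and the genes of mitochondrial DNA as quality lists, not as pathways. The labels name an mRNA kit, and its capture of histone transcripts was not tested, so the rise need not mean higher histone expression. H2BC5 rose from 8.21 ± 0.829 to 38.2 ± 2.02 FPKM, H4C9 from 19.0 ± 0.967 to 49.4 ± 1.5 FPKM and H2BC12 from 111 ± 7.97 to 291 ± 3.48 FPKM. Adjusted over the list alone, the G2/M counts were equal, 25 G1/S genes fell and 2 rose, 20 repair genes fell and 2 rose, and 11 histone genes rose.

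NF-kB and inflammatory genes fell in 19 of 21 cases, with 1 rise and 1 not passed (median -1.10, adjusted p = 1.48e-08; adjusted p = 0.151 with an estimated correlation). ICAM1 led, followed by CSF1 (62.8 ± 1.02 to 27.7 ± 0.528 FPKM), TNFAIP3 (8.97 ± 0.432 to 2.89 ± 0.242 FPKM) and NFKB1 (11.7 ± 0.320 to 5.44 ± 0.207 FPKM). The exception was the chemokine gene CXCL1, which rose from 18.9 ± 2.06 to 40.1 ± 1.55 FPKM. Of 12 antigen presentation genes, 7 fell, PSMB9 and B2M among them, 1 rose (HLA-E) and 4 did not pass (median -0.38, adjusted p = 0.0436; adjusted p = 0.227 with an estimated correlation). That call was lost without siSIRT6 replicate 2 (adjusted p = 0.0607), without the heptamer families (adjusted p = 0.0783) and in further alternatives named below. Apoptosis regulators fell in 13 of 22 cases, with 2 rises and 7 not passed (median -0.26, adjusted p = 0.0316; adjusted p = 0.171 with an estimated correlation). The apoptosis call was also lost without the heptamer families (median -0.19, adjusted p = 0.105) and with at least 5 FPKM. APAF1 and BCL2A1 fell, and BCL2L1 rose from 53 ± 4.57 to 101 ± 1.17 FPKM. Of 19 p53 targets, 11 fell, 2 rose and 6 did not pass (median -0.37, adjusted p = 0.0348; adjusted p = 0.197 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, fell from 131 ± 3.96 to 53.3 ± 0.714 FPKM, as did GDF15 and TNFRSF10B, and XPC rose. The p53 list was not past the threshold without control replicate 3 (adjusted p = 0.0662), with at least 5 FPKM (median -0.059, adjusted p = 0.389) or without the heptamer families (median -0.10, adjusted p = 0.759, range over alternatives 1.34e-05 to 0.759). Counts adjusted over the list alone were 19 inflammatory genes that fell and 1 that rose, while 9 antigen presentation genes fell and 1 rose, 13 apoptosis regulators fell and 3 rose, and 12 p53 targets fell and 2 rose.

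Mesenchymal genes rose in 16 of 25 cases, with 2 falls and 7 not passed (median 0.41, adjusted p = 3.64e-05; adjusted p = 0.219 with an estimated correlation). THBS1, COL5A1, MMP2 (17.8 ± 0.751 to 56.1 ± 1.09 FPKM) and TPM1 led the list, and SNAI1 was among the falls. Of 13 TGF-beta targets, 8 rose, PMEPA1 and LTBP2 among them, 3 fell and 2 did not pass (median 0.52, adjusted p = 0.0436; adjusted p = 0.311 with an estimated correlation). The TGF-beta call was lost without control replicate 3 (adjusted p = 0.0539) and without siKDM5C replicate 2 (adjusted p = 0.0709), with replicate number as a block (adjusted p = 0.0638), and in 6 more alternatives besides the estimated correlation (range 2.69e-05 to 0.311). Neuronal genes rose in 8 of 12 cases, with 1 fall and 3 not passed (median 0.64, adjusted p = 0.00375; adjusted p = 0.151 with an estimated correlation). Their median depended on the filter on low values and was 0.0010 with none and 1.02 with at least 5 FPKM. SCG2 rose from 0.877 ± 0.250 to 5.88 ± 0.154 FPKM, L1CAM from 13 ± 0.351 to 27.3 ± 0.332 FPKM and TUBB3 from 8.60 ± 0.507 to 23.4 ± 0.881 FPKM. Of 23 cholesterol synthesis genes, 12 rose, 1 fell (STARD4) and 10 did not pass (median 0.27, adjusted p = 0.000721; adjusted p = 0.0698 with an estimated correlation). HMGCS1 rose from 13.7 ± 0.646 to 21.8 ± 0.485 FPKM. Autophagy and lysosome genes rose in 16 of 33 cases, with WIPI2 and ULK1 in front, 4 falls and 13 not passed (median 0.13, adjusted p = 0.0303; adjusted p = 0.367 with an estimated correlation). The autophagy call was also lost with at least 5 FPKM (adjusted p = 0.0611), with protein-coding genes alone (0.057) and with the GC and length trend removed (0.0755; range 0.000179 to 0.367), each with a median of 0.13. Cytosolic ribosomal proteins fell in 29 of 62 cases, RPS24 among them, with 2 rises and 31 not passed (median -0.25, adjusted p = 0.000869; adjusted p = 0.667 with an estimated correlation). Of 11 LIN28B and let-7 target genes, 7 fell, 0 rose and 4 did not pass (median -0.30, adjusted p = 0.0199; adjusted p = 0.411 with an estimated correlation), with LIN28B itself from 3.15 ± 0.255 to 1.02 ± 0.0316 FPKM. Adjusted over the list alone, 17 autophagy genes rose and 4 fell, and the counts of the other 6 lists in this group were equal.

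Of the lists that did not pass after siSIRT6, 5 did so with some library left out. The MYC target list (median -0.19, adjusted p = 0.0512) passed without control replicate 1 (adjusted p = 0.0458), control replicate 2 (adjusted p = 0.0389), siSIRT6 replicate 3 (adjusted p = 0.0450) or siKDM5C replicate 3 (adjusted p = 0.0418). It also passed with replicate number as a block (adjusted p = 0.0474) and with only the groups compared (adjusted p = 0.0466). A pseudocount of 0.1 (adjusted p = 0.0495) and a minimum of 1 CPM (adjusted p = 0.0443) gave the call too. Histone methylation enzymes (median -0.24, adjusted p = 0.0522) passed without control replicate 1 (adjusted p = 0.0367), control replicate 2 (adjusted p = 0.0466) or siSIRT6 replicate 1 (adjusted p = 0.0395). MAPK output genes (median -0.24, adjusted p = 0.0522) passed without control replicate 2 (adjusted p = 0.0466). Interferon-stimulated genes (median -0.28, adjusted p = 0.0576) passed without control replicate 2 (adjusted p = 0.0490) or siSIRT6 replicate 3 (adjusted p = 0.0450). Genes of mitochondrial DNA (median -0.26, adjusted p = 0.0867) passed without control replicate 1 (adjusted p = 0.0409) or control replicate 2 (adjusted p = 0.0466).

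**Figure D2:**
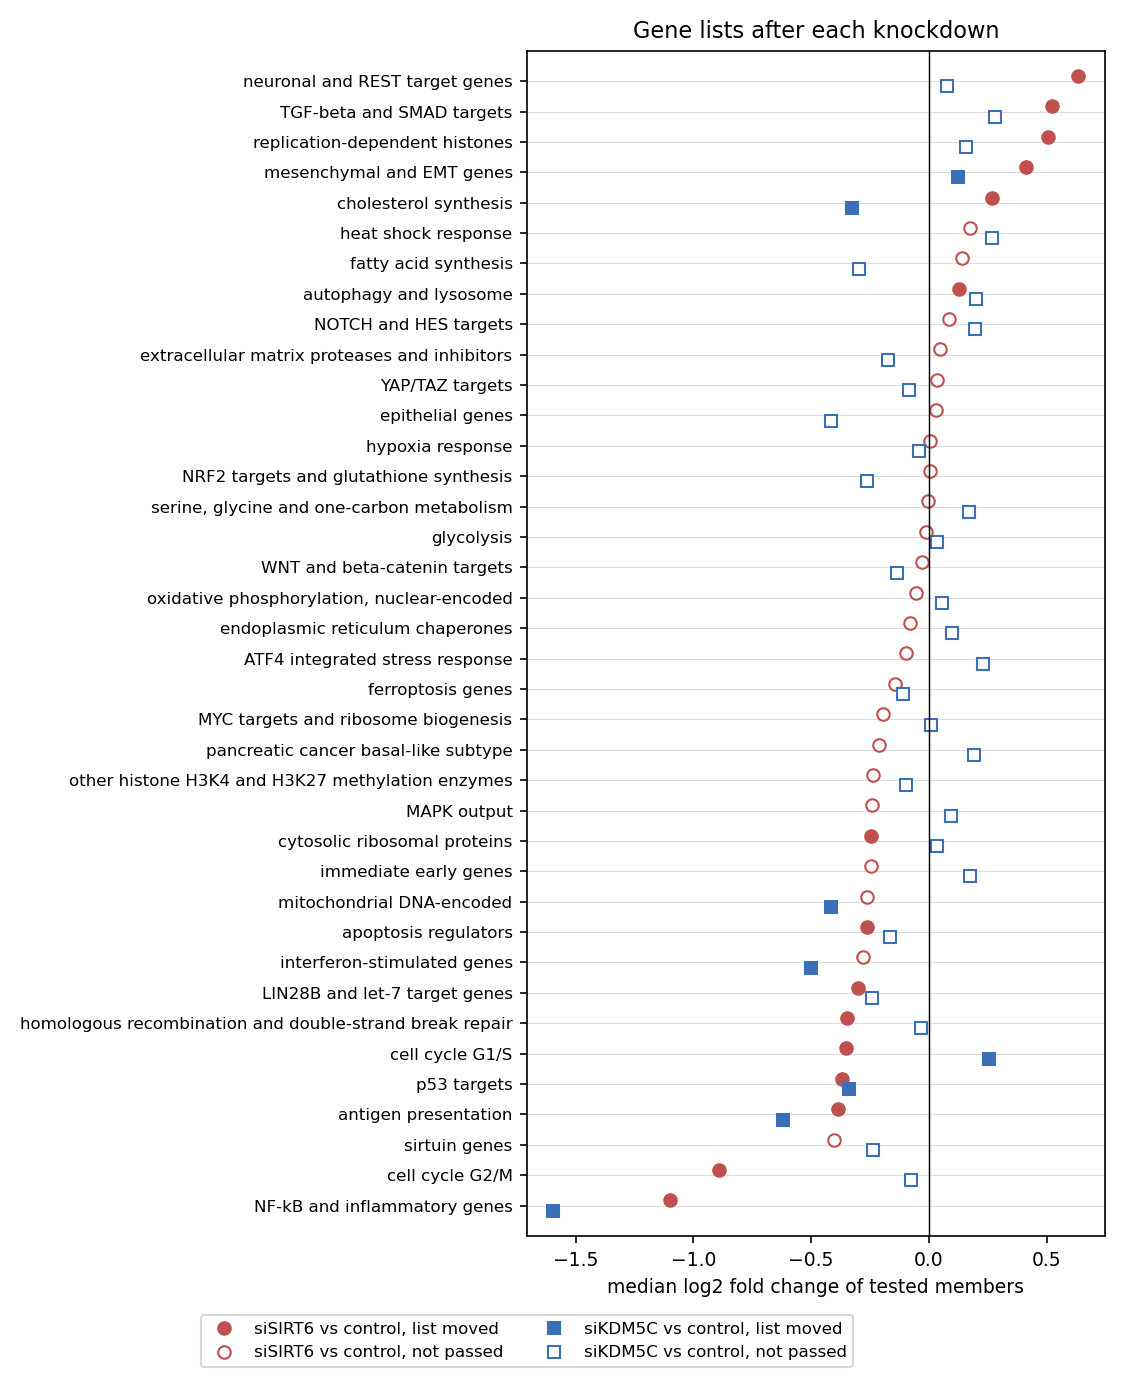
Median log2 fold change of the tested members of 38 gene lists, with circles for siSIRT6 against control and squares for siKDM5C against control, filled where the preset-correlation test had an adjusted p under 0.05. NF-kB and inflammatory genes lie at -1.10 and -1.59, and the G2/M list lies at -0.89 after siSIRT6 and -0.07 after siKDM5C.

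The comparison of siKDM5C with control asked the same of KDM5C. Inflammatory, interferon-stimulated and antigen presentation genes fell together, and most cholesterol synthesis genes fell too, while 18 of 35 G1/S genes rose. None of these lists passed with an estimated correlation. ICAM1 went from 633 ± 15 to 102 ± 5.88 FPKM, and SOD2, a mitochondrial superoxide dismutase induced by NF-kB, from 42.0 ± 0.403 to 8.25 ± 0.328 FPKM. IFIT2, an antiviral gene, went from 21.9 ± 1.25 to 6.40 ± 0.394 FPKM, and B2M, the light chain of class I antigen-presenting molecules, from 26.8 ± 1.43 to 12.2 ± 1.07 FPKM. DTL, a gene of DNA replication control, rose from 6.50 ± 0.326 to 14.8 ± 1.66 FPKM (SD, n = 3 throughout).

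After siKDM5C, 4134 genes rose and 4174 fell, 8308 in all, with a median size of 0.44 on the log2 scale, and 332 rises and 328 falls reached at least 1 log2. The 3 siKDM5C libraries lay entirely above or below the 3 controls for 55.7% of genes, against 10% by chance.

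The highest rise was that of thrombomodulin, THBD (ENSG00000178726, chromosome 20, 23045633 to 23049741), from 0.819 ± 0.0658 to 20.8 ± 1.96 FPKM, a log2 fold change of 3.58 (SE 0.07, adjusted p = 3.42e-08). The secreted hormone gene STC1 rose from 3.65 ± 0.145 to 29.7 ± 3.77 FPKM, the tropomyosin gene TPM4 from 8.00 ± 0.177 to 51.5 ± 3.37 FPKM, and AREG, which encodes a ligand of the EGF receptor, from 4.35 ± 0.161 to 27.8 ± 1.55 FPKM. NTN4 reached 76.1 ± 2.69 FPKM and OPN3 23.4 ± 2.29 FPKM, and BICD2, AKAP12, KIF1C-AS1 and the processed pseudogene FAM3C2P were the others among the 10 highest rises. KIF1C-AS1 overlaps KIF1C, and a processed pseudogene can collect reads of its parent gene, so both values are uncertain. The largest fall was that of EBI3 (ENSG00000105246, chromosome 19, 4229498 to 4237531), a cytokine subunit gene, from 26.4 ± 2.90 to 1.56 ± 0.407 FPKM (log2 fold change -3.43, SE 0.12, adjusted p = 3.68e-07). ANO9 fell to 1.08 ± 0.0766 FPKM, CCND1 to 34.8 ± 1.25 FPKM and CCL20 from 10.9 ± 0.882 to 1.18 ± 0.182 FPKM. PTGES, a prostaglandin E synthase gene, fell from 12.8 ± 0.667 to 1.22 ± 0.0870 FPKM and TNFAIP2 from 275 ± 6.67 to 45.6 ± 4.10 FPKM. PAPOLA (ENSG00000090060, chromosome 14, 96501433 to 96567111), the canonical poly(A) polymerase gene, fell from 13.3 ± 0.330 to 1.70 ± 0.148 FPKM and stood at 12.4 ± 0.160 FPKM in siSIRT6. ICAM1 with ICAM4-AS1 and CEND1 completed the 10 largest falls. The 3' UTR of TNFAIP2 holds the heptamer CAGGTTT, which is met more often in genes that fell after siKDM5C, and so do those of STC1 and BICD2, which rose. Of the 10 largest falls, TNFAIP2 was the only holder of that heptamer in a searched 3' UTR. ICAM1, CCND1, CCL20 and PTGES hold a related heptamer of the same family, as do THBD and OPN3 among the rises. EBI3, ANO9, PAPOLA and CEND1 hold none of the family. The 3' UTRs of BICD2 and TPM4, both among the rises, hold TCGGAGA, which is met more often in genes that rose after either knockdown. INHBB, which rose after siSIRT6 and fell after siKDM5C, holds TCGGAGA too.

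After siKDM5C 8 lists moved at the preset correlation, 2 up and 6 down, and 0 with an estimated correlation, where the lowest adjusted p = 0.114. NF-kB and inflammatory genes fell in 18 of 21 cases, with 1 rise (LIF, from 30.3 ± 1.23 to 39.5 ± 2.33 FPKM) and 2 not passed (median -1.59, adjusted p = 8.16e-10; adjusted p = 0.129 with an estimated correlation). SOD2, ICAM1, CSF1 (62.8 ± 1.02 to 12.1 ± 0.718 FPKM) and TNFAIP2 led it. Interferon-stimulated genes fell in 17 of 22 cases, with 1 rise (MX2) and 4 not passed (median -0.50, adjusted p = 2.53e-05; adjusted p = 0.114 with an estimated correlation). IFIT3 fell from 9.27 ± 0.362 to 2.11 ± 0.370 FPKM, IFIH1 from 10.1 ± 1.05 to 2.72 ± 0.280 FPKM and PARP14 from 14.9 ± 1.07 to 5.31 ± 0.333 FPKM. Of 12 antigen presentation genes, 10 fell, 0 rose and 2 did not pass (median -0.62, adjusted p = 0.000408; adjusted p = 0.114 with an estimated correlation), with B2M, PSMB9, TAP1 (20.7 ± 0.408 to 10.4 ± 1.15 FPKM) and PSMB10 first. Of the 13 genes of mitochondrial DNA, 8 fell, MT-ND2 and MT-ND4 among them, 0 rose and 5 did not pass (median -0.42, adjusted p = 0.00766; adjusted p = 0.559 with an estimated correlation), and the call was lost once the GC and length trend was removed (median -0.34, adjusted p = 0.0846, range 0.0017 to 0.559). Adjusted over the list alone, 19 inflammatory genes fell and 2 rose, 9 mitochondrial genes fell, and the interferon and antigen presentation counts were equal.

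Cholesterol synthesis genes fell in 15 of 23 cases after siKDM5C, with 3 rises and 5 not passed (median -0.33, adjusted p = 0.00969; adjusted p = 0.114 with an estimated correlation). STARD4 fell from 6.2 ± 0.800 to 1.94 ± 0.266 FPKM and MSMO1 from 50.9 ± 6.05 to 20.9 ± 3.59 FPKM. INSIG1 and PMVK were among the rises. Of 35 G1/S genes, 18 rose, 3 fell and 14 did not pass (median 0.26, adjusted p = 0.0115; adjusted p = 0.114 with an estimated correlation). The G1/S call was also lost with at least 5 FPKM (median 0.16, adjusted p = 0.182) and without the heptamer families (median 0.26 as before, adjusted p = 0.119; range 6.87e-06 to 0.182). CHAF1A rose from 4.40 ± 0.480 to 9.05 ± 0.571 FPKM and GINS3 from 1.14 ± 0.0474 to 2.42 ± 0.102 FPKM, while RFC3, UHRF1 and CCNE1 fell. Of 19 p53 targets, 12 fell, with CDKN1A at 55.8 ± 2.43 FPKM and ZMAT3 at 2.34 ± 0.609 FPKM, 3 rose and 4 did not pass (median -0.34, adjusted p = 0.0274; adjusted p = 0.206 with an estimated correlation). The p53 call was lost without control replicate 3 (adjusted p = 0.0588), without the heptamer families (median -0.45, adjusted p = 0.356) and with at least 5 FPKM. Mesenchymal genes rose in 11 of 25 cases, MMP14, THBS1 and COL5A1 first, with 3 falls and 11 not passed (median 0.13, adjusted p = 0.0462; adjusted p = 0.559 with an estimated correlation). The mesenchymal list was not past the threshold without control replicate 2 (adjusted p = 0.0533), control replicate 3 (adjusted p = 0.0629), siSIRT6 replicate 1 (adjusted p = 0.0511), siSIRT6 replicate 2 (adjusted p = 0.0503), siKDM5C replicate 2 (adjusted p = 0.0542) or siKDM5C replicate 3 (median 0.074, adjusted p = 0.0565), with replicate number as a block (adjusted p = 0.054) or with the GC and length trend removed (median 0.053, adjusted p = 0.208; range 5.37e-05 to 0.559). In counts adjusted over the list alone, 19 G1/S genes rose and 3 fell, 13 p53 targets fell and 3 rose, and the cholesterol and mesenchymal counts were equal.

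The G2/M list did not pass after siKDM5C, with 10 of 33 members lower, 5 higher and 18 not passed (median -0.07, adjusted p = 0.573). Among its members BIRC5 rose from 8.74 ± 0.158 to 16.7 ± 1.91 FPKM and KIF23 fell from 15.7 ± 0.314 to 10.4 ± 0.378 FPKM. Heat shock genes, 6 of 10 up and 0 down (median 0.27, adjusted p = 0.0512), passed without control replicate 3 (adjusted p = 0.0484), siKDM5C replicate 2 (adjusted p = 0.0459) or siKDM5C replicate 3 (adjusted p = 0.0200). Epithelial genes, 7 of 14 down and 2 up (median -0.42, adjusted p = 0.0987), passed without siKDM5C replicate 3 (adjusted p = 0.0369), and cytosolic ribosomal proteins, with 12 of 62 up and 4 down (median 0.03, adjusted p = 0.488), passed without siKDM5C replicate 2 (median 0.12, adjusted p = 0.0220).

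**Figure D3:**
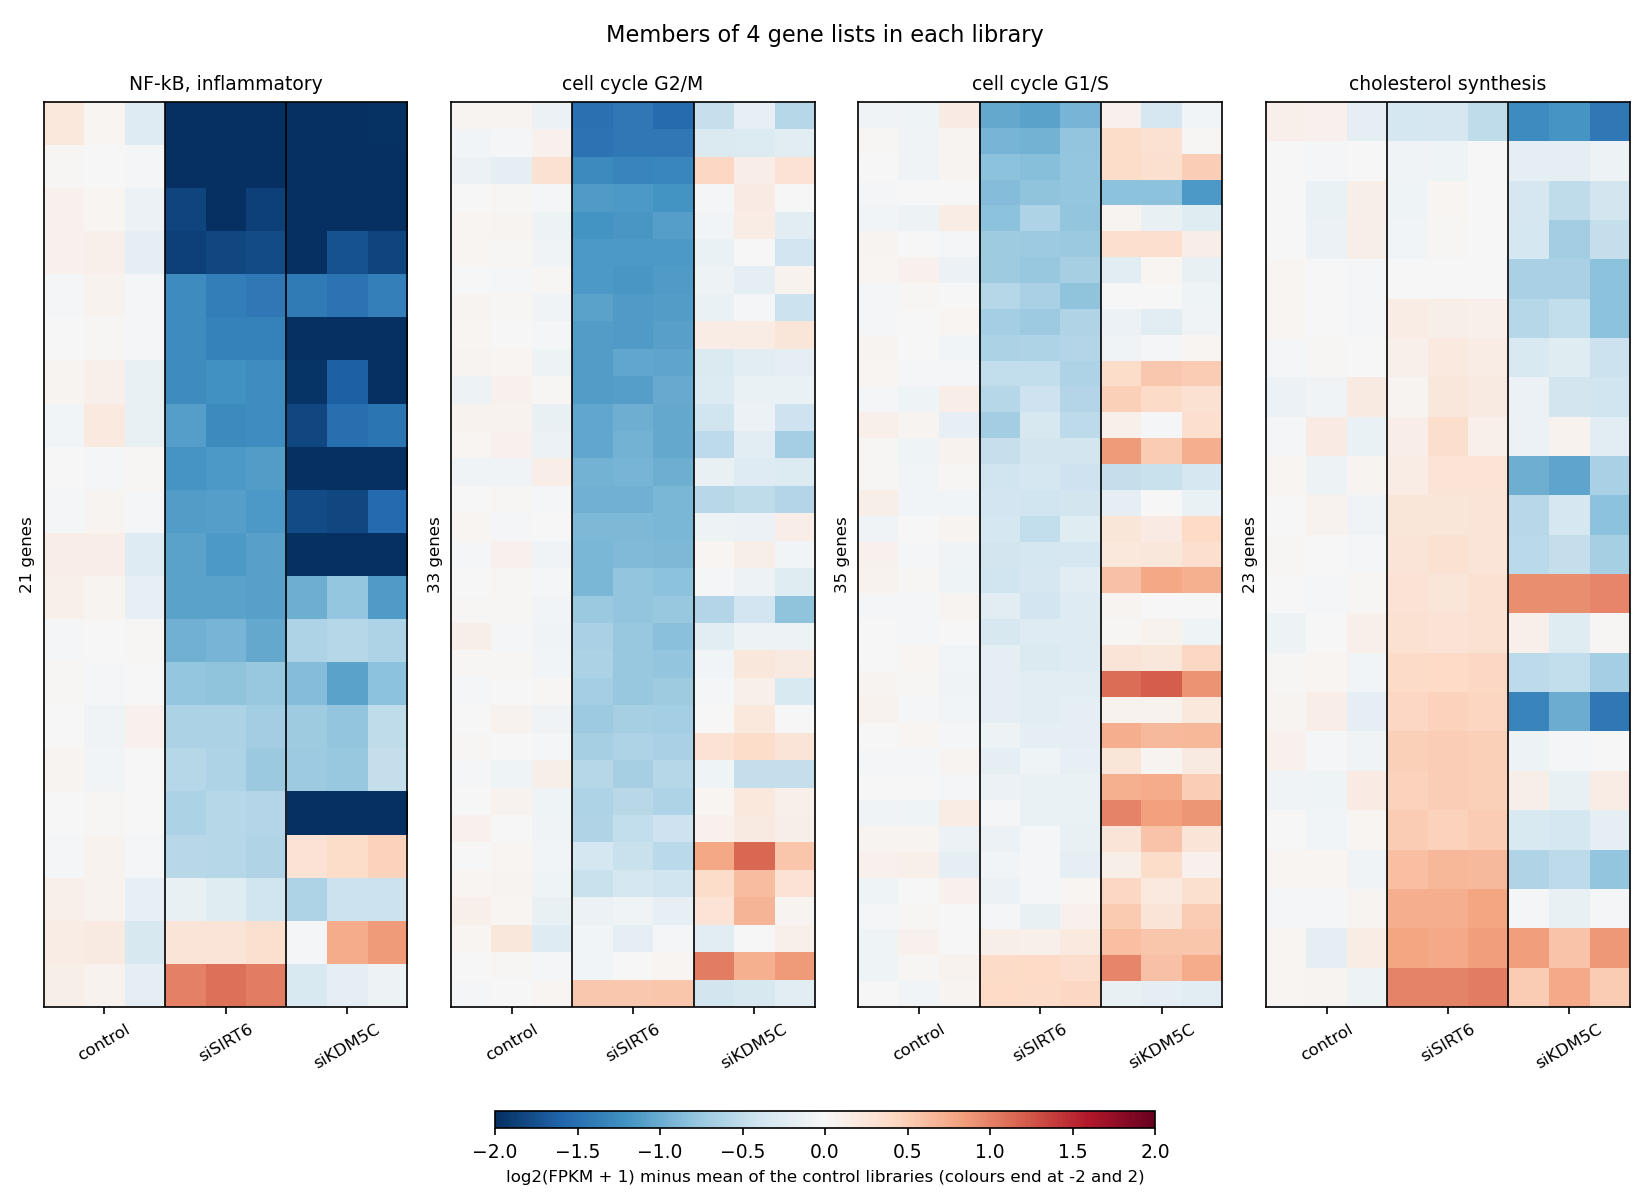
Log2(FPKM + 1) of each tested member of the NF-kB, G2/M, G1/S and cholesterol synthesis lists in the 9 libraries, minus the gene's control mean, with colours that end at -2 and 2 and members ordered by their change after siSIRT6. Members of the NF-kB list are lower in both knockdowns (medians -1.10 and -1.59), and G1/S members are lower in siSIRT6 (median -0.35) and higher in siKDM5C (median 0.26).

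The direct comparison of siSIRT6 with siKDM5C asked where the knockdowns differ, and its fold changes use no control library, although its variance came from all 9 libraries. Genes of the cell cycle were lower in siSIRT6 and genes of sterol and fatty acid synthesis were higher, although the fatty acid list did not pass with an estimated correlation. KIF2C, a mitotic kinesin gene, stood at 10.1 ± 0.106 FPKM in siSIRT6 and 26.3 ± 1.01 FPKM in siKDM5C, and FEN1 at 13.9 ± 0.429 and 33.6 ± 2.32 FPKM. HMGCS1, an early enzyme gene of sterol synthesis, stood at 21.8 ± 0.485 and 8.49 ± 0.879 FPKM, and the fatty acid desaturase gene SCD at 720 ± 9.90 and 304 ± 14 FPKM (SD, n = 3 throughout).

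Between the knockdowns 3009 genes were higher and 3433 lower in siSIRT6, 6442 in all, with 164 and 174 differing by at least 1 log2. The 3 siSIRT6 libraries lay entirely above or below the 3 siKDM5C libraries for 51.7% of genes, against 10% by chance. Median-of-ratios scaling gave 3449 higher and 2990 lower. PAPOLA (log2 fold change 2.31, adjusted p = 4.48e-07), C15orf48, KDM5C, LYNX1 and RAB27B were higher in siSIRT6 by the most, of which PAPOLA, C15orf48 and KDM5C stood near control in siSIRT6 and low in siKDM5C. C15orf48 stood at 122 ± 0.548 FPKM in control, 124 ± 2.92 in siSIRT6 and 29.5 ± 2.77 in siKDM5C, and RAB27B at 4.55 ± 0.703, 14.3 ± 0.472 and 3.25 ± 1.15 FPKM. THBD (log2 fold change -2.82, adjusted p = 4.59e-07), NEAT1, POLE3, AMPD3 and SIRT6 were lower in siSIRT6 by the most, of which THBD had risen in siKDM5C and the others had fallen in siSIRT6. POLE3, a gene of a DNA polymerase subunit that overlaps C9orf43, stood at 26.0 ± 0.207 FPKM in control, 6.57 ± 0.185 in siSIRT6 and 28.8 ± 3.14 in siKDM5C. The 3' UTR of POLE3 holds ACTTGTT, and that of RAB27B holds CAGGTTT.

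Between the knockdowns 18 lists differed at the preset correlation, 10 higher and 8 lower in siSIRT6, of which 5 also passed with an estimated correlation. Those 5 were the G1/S genes (31 of 35 lower, 1 higher, 3 not passed, median -0.60, adjusted p = 6.18e-12; adjusted p = 0.00575 with an estimated correlation), cholesterol synthesis (19 of 23 higher, 1 lower, 3 not passed, median 0.53, adjusted p = 1.28e-09; adjusted p = 0.00720 with an estimated correlation), G2/M genes (29 of 33 lower, 1 higher, 3 not passed, median -0.84, adjusted p = 2.04e-14), neuronal genes (11 of 12 higher, 1 not passed, median 0.50, adjusted p = 2.63e-05) and histones (11 of 16 higher, 1 lower, 4 not passed, median 0.47, adjusted p = 0.000172). The G2/M, neuronal and histone lists each had adjusted p = 0.0433 with an estimated correlation. The histone median depended on the filter on low values, and its sign turned with no filter. ORC1 and MCM10 were lower with the G1/S genes, TPX2 with the G2/M genes, and CYP51A1 was higher with the sterol genes. Interferon-stimulated genes were higher in siSIRT6 in 14 of 22 cases and lower in 2 (median 0.41, adjusted p = 0.000161; adjusted p = 0.0652 with an estimated correlation), and antigen presentation genes in 8 of 12 and 0 (median 0.42, adjusted p = 0.00132; adjusted p = 0.0842 with an estimated correlation). Inflammatory genes were higher in 10 of 21 cases, SOD2 and CSF1 first, and lower in 2, LIF and NFKB1 (median 0.23, adjusted p = 0.00265; adjusted p = 0.334 with an estimated correlation). The inflammatory call was also lost without the heptamer families (median 0.18, adjusted p = 0.0725). Fatty acid synthesis genes were higher in 8 of 14 cases and lower in 0 (median 0.32, adjusted p = 0.000570; adjusted p = 0.177 with an estimated correlation). With p-values adjusted over the list alone, 32 G1/S genes were lower, 20 cholesterol and 9 fatty acid genes were higher, 1 neuronal gene was lower, and the other counts in this group were equal.

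The remaining 9 lists lost their call with an estimated correlation. Mesenchymal genes were higher in siSIRT6 in 16 of 25 cases and lower in 1, MMP14 (median 0.25, adjusted p = 0.000346; adjusted p = 0.262 with an estimated correlation). Epithelial genes were higher in 6 of 14 cases, CLDN1, KRT8 and KRT19 among them, and lower in 2 (median 0.12, adjusted p = 0.0177; adjusted p = 0.395 with an estimated correlation). The epithelial call was lost without siKDM5C replicate 2 (median 0.073, adjusted p = 0.0616) and without the heptamer families (median 0.12, adjusted p = 0.0971). CLDN1 stood at 34.9 ± 2.41 FPKM in control, 67.7 ± 0.776 in siSIRT6 and 22.8 ± 1.72 in siKDM5C. NRF2 targets were higher in 9 of 18 cases and lower in 4 (median 0.18, adjusted p = 0.0281; adjusted p = 0.343 with an estimated correlation), a call lost without siKDM5C replicate 1 (adjusted p = 0.0561). The NRF2 call was also lost without the heptamer families (median 0.055, adjusted p = 0.119). Protein-coding genes alone (adjusted p = 0.0597) and a minimum of 1 CPM (adjusted p = 0.0537) lost it too. Ribosomal proteins were lower in 28 of 62 cases, RPS6 first, and higher in 0 (median -0.29, adjusted p = 1.01e-06; adjusted p = 0.449 with an estimated correlation). MYC targets were lower in 15 of 31 cases and higher in 2 (median -0.16, adjusted p = 0.00249; adjusted p = 0.0566 with an estimated correlation), with DKC1 at 18.4 ± 0.451 and 40.2 ± 2.60 FPKM and MYC itself at 19.7 ± 0.834 and 33.4 ± 1.05 FPKM. Break repair genes were lower in 12 of 26 cases, FANCI and FANCD2 first, and higher in 1 (median -0.29, adjusted p = 0.000939; adjusted p = 0.334 with an estimated correlation). The repair median was -0.19 without siKDM5C replicate 2 (adjusted p = 0.0103) and -0.078 with at least 5 FPKM, where the call was lost (adjusted p = 0.299, range 2.47e-05 to 0.334). Immediate early genes were lower in 8 of 13 cases, ZFP36 and EGR1 among them, and higher in 1 (median -0.40, adjusted p = 0.00221; adjusted p = 0.194 with an estimated correlation). Histone methylation enzymes were lower in 9 of 18 cases and higher in 1 (median -0.21, adjusted p = 0.00690; adjusted p = 0.334 with an estimated correlation), with ASH2L, a subunit of lysine 4 methyltransferases, at 1.47 ± 0.141 and 3.83 ± 0.219 FPKM. The methylation enzyme call was also lost without the heptamer families (median -0.12, adjusted p = 0.414) and with at least 5 FPKM. Genes of the ATF4 stress response were lower in 12 of 25 cases, ASNS first, and higher in 2 (median -0.16, adjusted p = 0.0130; adjusted p = 0.112 with an estimated correlation), with a median of -0.25 without siKDM5C replicate 2. Adjusted over the list alone, 31 ribosomal, 16 MYC target and 10 methylation enzyme genes were lower, 3 mesenchymal genes were lower, and the other counts in this group were equal. Genes of mitochondrial DNA (median 0.14, adjusted p = 0.0578) passed without control replicate 3 (adjusted p = 0.0313), siSIRT6 replicate 3 (adjusted p = 0.0446) or siKDM5C replicate 1 (median 0.28, adjusted p = 0.0183), and had a median of 0.079 without siKDM5C replicate 3 (adjusted p = 0.23). Serine and one-carbon genes (median -0.28, adjusted p = 0.0512) passed without siSIRT6 replicate 2 (adjusted p = 0.0427) or siKDM5C replicate 3 (adjusted p = 0.0294).

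The last comparison asked how far both knockdowns changed the same genes. Past the threshold in both, 4990 genes moved the same way, 2556 up and 2434 down, and 471 moved in opposite directions, so that 91.4% of the genes changed by both went the same way. Independent lists of these sizes would share 2110 genes the same way and 2109 in opposite directions, a count that leaves out the effect of the shared controls. Pearson's r of the log2 fold changes across genes was 0.66, against 0.50 in 100 simulations without effect against the same controls, where the shared controls alone create a correlation. Genes are not independent replicates, so no p-value is attached. The covariance was 0.148, against 0.0097 in the simulations and at most 0.0111.

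Among the genes that moved the same way most, NTN4 (ENSG00000074527, chromosome 12, 95657807 to 95791152) rose by 2.59 on the log2 scale in either knockdown, and ANO9 (ENSG00000185101, chromosome 11, 417933 to 442011) fell by 2.51 after siSIRT6 and by 2.82 after siKDM5C. CPA4 rose by 3.84 and 2.18, OPN3 by 3.28 and 2.35, KMO by 3.06 and 2.09, and KIF1C-AS1 by 2.37 and 2.27. In opposite directions, LYNX1 and its readthrough gene LYNX1-SLURP2, LPCAT2, INHBB and LXN rose after siSIRT6 and fell after siKDM5C. LXN, a carboxypeptidase inhibitor gene, stood at 29.2 ± 3.63 FPKM in control, 61.9 ± 1.10 in siSIRT6 and 17.9 ± 2.15 in siKDM5C, and INHBB, a subunit gene of activins and inhibins, at 8.16 ± 0.577, 15.9 ± 1.04 and 4.66 ± 0.444 FPKM. PCLAF, a factor gene that binds the replication clamp, fell after siSIRT6 and rose after siKDM5C, at 7.96 ± 0.731, 4.32 ± 0.104 and 14.7 ± 0.918 FPKM. LYNX1 shares sequence with LYNX1-SLURP2, and LXN overlaps GFM1, so these values are less certain.

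**Figure D4:**
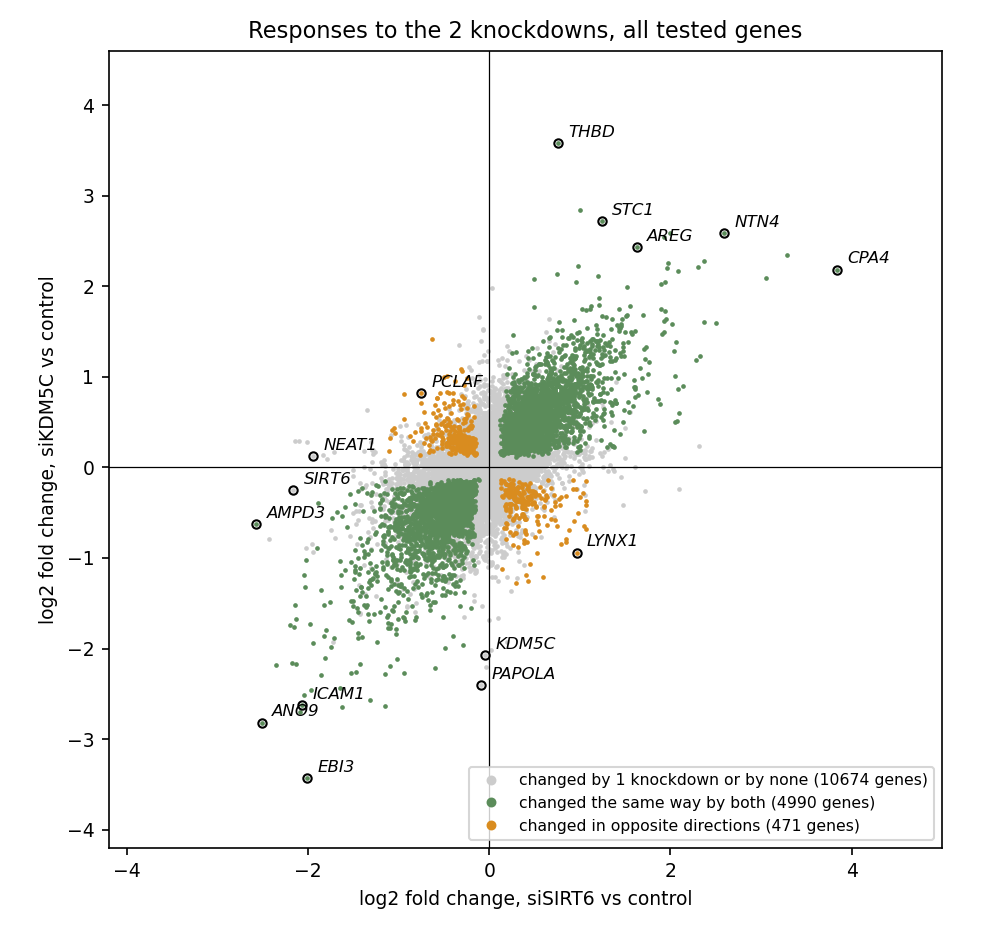
Log2 fold change of each of 16135 genes after siSIRT6 (x axis) and after siKDM5C (y axis), with colours for 4990 genes changed the same way, 471 changed in opposite directions and, in grey, all other genes. Most genes changed by both lie in the quadrants where both knockdowns raise or both lower them.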

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

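The fits without the leading heptamer families were chosen after the results were seen, and the heptamer tests were set down before their outcome was known. The cholesterol synthesis list and the G1/S list drew attention because the knockdowns moved each of them in opposite directions against the same controls. For cholesterol synthesis the siSIRT6 effect minus the siKDM5C effect had a median of 0.525 on the log2 scale (medians 0.27 and -0.33 against control). For G1/S genes it was -0.60 (medians -0.35 and 0.26). The difference itself was tested, with adjusted p = 1.28e-09 for cholesterol synthesis and 6.18e-12 for G1/S genes. Passing this test was part of the rule that flagged both lists, so it is no separate support. Over the alternatives the cholesterol difference was 0.49 to 0.75 with adjusted p from 2.71e-15 to 0.0072, and the G1/S difference was -0.68 to -0.56 with adjusted p from 3.93e-19 to 0.00575. The changes against control lost their calls under some alternatives. After siKDM5C the rise of the G1/S list had medians of 0.16 to 0.29 with adjusted p from 6.87e-06 to 0.182, and after siSIRT6 the rise of the cholesterol list had medians of 0.25 to 0.31 with adjusted p from 3.61e-06 to 0.0698. The falls that oppose them had adjusted p from 1.87e-08 to 0.0512 for G1/S genes after siSIRT6 and from 2.67e-05 to 0.114 for cholesterol synthesis after siKDM5C.

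Genes that differ between the knockdowns may include off-target genes of the siRNAs, which can lower transcripts that pair with their first bases (the seed) in the 3' UTR. The heptamer with the strongest shift between the knockdowns in favour of siKDM5C was ACTTGTT (z = -15.72, highest of the permutations 5.16), which 36.3% of the 146 genes with a searched 3' UTR that fell at least 1 log2 after siSIRT6 hold, against 14.1% of genes that did not pass. The strongest in favour of siSIRT6 was CAGGTTT (z = 11.02), which 36.0% of the 161 genes that fell as far after siKDM5C hold, against 13.7%. Both heptamers were picked from fold changes of the same libraries, and the shares take no account of the UTR's length. They are no support beyond the z values. Matches to the leading heptamer families in the members' 3' UTRs are not the whole of the list differences. Outside the families, 12 cholesterol synthesis members had a median of 0.49 (adjusted p = 3.32e-09, within the range above) and 11 G1/S members of -0.61 (adjusted p = 6.82e-07). The families leave out related heptamers, such as AACTTGT (z = -6.30 after siSIRT6 against control) and TAGGTTT (z = -5.76 after siKDM5C against control). Other direct matches, seed effects through other genes, and loss of SIRT6 or of KDM5C itself stay open as untested explanations. The siRNA sequences, which would settle the seeds, are not given in the sources used here.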

How the results depend on the processing

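The alternatives chosen after seeing the data were limma-voom on the recovered reads, protein-coding genes alone, genes outside the leading heptamer families, and removal of the trend on GC content and gene length. With at least 5 FPKM in 3 libraries, 9446 genes were tested, and 5367 changed after siSIRT6 and 5418 after siKDM5C, with 9 and 5 lists moved. Without the heptamer families 9844 genes were tested, of which 5029 have no searched 3' UTR, and 4197 changed after siSIRT6, 4257 after siKDM5C and 3022 between the knockdowns, with 2437 changed the same way by both and 5 lists moved after siKDM5C. With at least 5 FPKM, the changed share of tested genes was larger than in the reported fit after either knockdown. The lower gene counts there follow from fewer genes tested. Without the heptamer families the share was smaller in each comparison, so fewer genes tested accounts for only part of the drop. A test against a 1.5-fold change left 768, 741 and 352 genes in the 3 comparisons, and an adjusted p under 0.01 left 3999 between the knockdowns and 3237 changed the same way, as stricter thresholds must lower them. No filter on low values gave 13 lists after siKDM5C, and the cause was not tested.

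The list test mattered most for the lists. Camera with an estimated correlation gave 0 lists after siSIRT6, 0 after siKDM5C and 5 between the knockdowns, and fry gave 32, 29 and 31. The hypoxia list after siKDM5C had a median of -0.042 while fry called it up (adjusted p = 0.00607, against 0.00607 to 0.999 over its alternatives). Without the heptamer families the p53 list lost its call after siSIRT6 with a smaller median (-0.10 in place of -0.37), and after siKDM5C with a larger one (-0.45 in place of -0.34, adjusted p = 0.356, range 2.71e-05 to 0.356), where fewer genes were tested. Medians in brackets are those of the alternative and then the reported ones. The LIN28B and TGF-beta lists have 3 members each outside the families, fewer than the 5 needed, and were not tested there. Without these families, calls were also lost after siSIRT6 for antigen presentation (-0.29, -0.38) and apoptosis (-0.19, -0.26), after siKDM5C for G1/S (0.26, 0.26) and mesenchymal genes (0.33, 0.13), and between the knockdowns for NF-kB (0.18, 0.23), NRF2 (0.055, 0.18), epithelial (0.12, 0.12) and methylation enzyme genes (-0.12, -0.21). Calls were gained after siSIRT6 for fatty acid synthesis (0.36, 0.14), MYC targets (-0.25, -0.19) and methylation enzymes (-0.35, -0.24), and between the knockdowns for serine and one-carbon genes (-0.51, -0.28) and mitochondrial genes (0.14, 0.14). With at least 5 FPKM, the LIN28B (-0.26, -0.30), TGF-beta (0.52, 0.52), antigen presentation (-0.29, -0.38), apoptosis (-0.26, -0.26), autophagy (0.13, 0.13) and p53 (-0.059, -0.37) calls were lost after siSIRT6, the G1/S (0.16, 0.26), mesenchymal (0.083, 0.13) and p53 (-0.43, -0.34) calls after siKDM5C, and the repair (-0.078, -0.29) and methylation enzyme (-0.21, -0.21) calls between the knockdowns. With the GC and length trend removed (11207 genes), the TGF-beta (0.37, 0.52), antigen presentation (-0.34, -0.38), autophagy (0.13, 0.13) and p53 (-0.34, -0.37) calls were lost after siSIRT6 and the mesenchymal (0.053, 0.13) and mitochondrial (-0.34, -0.42) calls after siKDM5C, while MYC targets (-0.18, -0.19) and methylation enzymes (-0.27, -0.24) gained one after siSIRT6. Protein-coding genes alone lost the TGF-beta, antigen presentation and autophagy calls after siSIRT6, the mesenchymal call after siKDM5C and the NRF2 call between the knockdowns, with unchanged medians. The TGF-beta call after siSIRT6 was lost with a minimum of 1 CPM (0.29, 0.52), the replicate block, the fit of only the groups compared and upper-quartile scaling. The mesenchymal call after siKDM5C was lost with the first of these (0.075, 0.13), the block and the fit of the groups compared, and the NRF2 call between the knockdowns with a minimum of 1 CPM. With no filter the histone median was 0.015 after siSIRT6 and -0.0069 between the knockdowns, against 1.03 and 1.02 with at least 5 FPKM, and all 4 passed.

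With 1 library left out, 6698 to 8767 genes changed after siSIRT6, 6873 to 8324 after siKDM5C and 4820 to 6873 between the knockdowns, with 13 to 20, 7 to 9 and 17 to 19 lists, and 4000 to 5099 genes changed the same way. The log2 fold change of SIRT6 after siSIRT6 was -2.27 to -2.07 and that of KDM5C after siKDM5C -2.12 to -2.02. Of the verdicts on named genes, 4786 stayed, 3 gained a call and 2 lost it. Apart from each target in the other knockdown, these genes had been chosen for passing the test. The count is therefore no measure of stability for other genes. The gains were KDM5C after siSIRT6 and SIRT6 after siKDM5C once the GC and length trend was removed (log2 fold change -0.15, adjusted p = 0.00567, range 0.00567 to 0.945, and -0.30, 0.0169, range 0.0169 to 0.308), and SIRT6 after siKDM5C without control replicate 2 (adjusted p = 0.0337). The losses were MT-ND4 and MT-CO2 after siKDM5C with no filter (adjusted p = 0.162, range 8.12e-05 to 0.162, and 0.332, range 2.65e-05 to 0.332). Of verdicts on lists that had moved 852 stayed and 89 were lost, and of those on other lists 1542 stayed, 105 gained a call and 1 reversed. With replicate number as a block, 8130, 8245 and 6386 genes changed. The plan did not treat the replicate numbers as pairs, because the series states no pairing. Of 9 pairs of libraries with the same number, 1 correlated above 0.1, while libraries with different numbers reached 0.43 (control replicate 3 and siKDM5C replicate 1). Against this, 5 of the 9 libraries correlated best with a library of their own number. Replicates of 1 group differed by 2.02 to 19.6 times counting noise, and control replicate 3 by 11.6 and 12.7 from the other controls, which differed by 2.67. The siSIRT6 pairs differed by 2.02 to 3.36 times and the siKDM5C pairs by 13.7 to 19.6 times. The reported fit pooled these spreads. Fits of only the groups compared gave 9100 changed genes after siSIRT6 and 7027 after siKDM5C. The edgeR and DESeq2 alternatives were not run, since the files hold FPKM, and scaling by library size alone is the reported setting.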

Other observations

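The test on the shared controls and the choice of genes in the heptamer test of the whole cause were chosen after the results were seen. Several genes outside the lists that moved changed in both knockdowns. DKK1, a secreted WNT inhibitor, rose from 36.8 ± 2.33 FPKM in control to 152 ± 1.02 in siSIRT6 and 112 ± 5.68 in siKDM5C. Among matrix proteases, the urokinase gene PLAU went from 768 ± 26.5 to 277 ± 5.5 and 300 ± 22.9 FPKM, the shedding protease gene ADAM17 from 9.82 ± 0.564 to 2.86 ± 0.122 and 4.77 ± 0.307 FPKM, and the collagenase gene MMP1 rose from 2.72 ± 0.0896 to 7.11 ± 0.222 and 11.8 ± 1.17 FPKM. The aldolase gene ALDOC fell from 15.5 ± 0.967 to 7.91 ± 0.758 and 5.02 ± 0.444 FPKM, and GCH1, which encodes the first enzyme of tetrahydrobiopterin synthesis, from 4.49 ± 0.359 to 1.51 ± 0.246 and 1.82 ± 0.165 FPKM. Of the other sirtuins, SIRT1 fell from 15.9 ± 1.06 to 11.8 ± 0.293 and 9.33 ± 1.49 FPKM, and SIRT7 from 13.1 ± 0.587 to 8.38 ± 0.31 and 11 ± 1.25 FPKM. NDRG1, a hypoxia-induced gene, stood at 4.72 ± 0.253, 3.63 ± 0.0364 and 11.1 ± 0.343 FPKM (SD, n = 3 throughout).

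The lists with fewer than 5 tested members were not tested as lists. Of the 4 KDM5 and JARID2 genes, KDM5B fell from 6.8 ± 0.0409 to 5.75 ± 0.0998 and 5.23 ± 0.204 FPKM, KDM5A did not pass in either knockdown, and JARID2 rose after siKDM5C (adjusted p = 0.0239). Of 2 germline genes MEIOC rose in both knockdowns and SYCP2 did not pass. Of 3 genes of the classical subtype, AGR2 rose from 28 ± 0.614 to 47.2 ± 1.15 and 44.2 ± 0.471 FPKM, and after siKDM5C GATA6 fell and CEACAM6 rose. The endocrine gene CHGB rose in both knockdowns. Of 3 fibroblast genes, COL1A1 went from 16 ± 0.514 to 41.4 ± 0.959 FPKM after siSIRT6 and stood at 15.6 ± 1.12 FPKM after siKDM5C, COL3A1 rose in both, and FBLN1 fell after siSIRT6. Of 2 leukocyte genes CD14 fell in both and CD68 rose after siKDM5C, and the endothelial gene ESAM fell after siSIRT6 and rose after siKDM5C. The acinar and erythroid lists had 0 tested members.

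The following 14 lists moved in none of the 3 comparisons at the preset correlation with all libraries, and adjusted p is given for siSIRT6, siKDM5C and the direct comparison in turn. Of 7 sirtuin genes 4 fell and 1 rose after siSIRT6, and 2 fell and 1 rose after siKDM5C (0.296, 0.647, 0.409). Glycolysis had 7 of 22 up and 7 down, then 6 up and 4 down (0.999, 0.573, 0.48), hypoxia 2 of 19 up and 6 down, then 6 and 6 (0.809, 0.959, 0.785), and nuclear oxidative phosphorylation 5 of 35 up and 8 down, then 7 and 6 (0.834, 0.81, 0.547). Serine and one-carbon genes had 1 of 11 up and 2 down, then 5 and 2 (0.762, 0.247, 0.0512), ferroptosis genes 4 of 18 up and 6 down, then 3 and 9 (0.417, 0.247, 0.681), and endoplasmic reticulum chaperones 2 of 19 up and 6 down, then 6 and 5 (0.394, 0.863, 0.228). Heat shock genes had 5 of 10 up and 3 down, then 6 and 0 (0.373, 0.0512, 0.157), MAPK output genes 3 of 17 up and 10 down, then 7 and 7 (0.0522, 0.863, 0.0654), and matrix proteases 6 of 13 up and 5 down, then 5 and 7 (0.999, 0.586, 0.929). YAP and TAZ targets had 8 of 19 up and 8 down, then 4 and 9 (0.834, 0.404, 0.105), and WNT targets 2 of 6 up and 1 down, then 2 and 2 (0.762, 0.863, 0.109). NOTCH targets had 2 of 8 up and 3 down, then 4 and 2 (0.834, 0.573, 0.547), and basal-like genes 3 of 7 up and 3 down in either knockdown (0.706, 0.573, 0.547). The median and the mean had different signs for the basal-like (-0.21 and 0.23), WNT, hypoxia, YAP and protease lists after siSIRT6 and for the hypoxia, chaperone and oxidative phosphorylation lists after siKDM5C. Adjusted over the list alone, 8 ferroptosis, 6 oxidative phosphorylation and 4 basal-like genes fell after siSIRT6. After siKDM5C 2 sirtuin genes rose and 3 fell, and 5 oxidative phosphorylation, 8 MAPK output and 4 basal-like genes rose. The other counts against control in this group were equal.

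Both knockdowns changed 4990 genes the same way. Chance values of the 3 shared controls are argued against by the covariance of the responses, 0.148 against at most 0.0111 in simulations without effect, and 1 control library out of place by the count of 4000 without control replicate 2, the lowest with a control left out. A short RNA in the control cells may contribute, since the heptamer TCGGAGA had z = 9.62 (highest of the permutations 4.72). It is held by 7.76% of 245 genes with a searched 3' UTR that rose at least 1 log2 after siSIRT6 and by 11% of 209 after siKDM5C, against 1.46% and 1.35% of genes that did not pass. The heptamer was picked from these fold changes, so the shares are no support beyond the z value. Direct matches to the leading heptamers as the whole cause are argued against by a covariance of 0.107. It came from 2777 genes with a searched 3' UTR that lacks the leading heptamer families and the 10 leading heptamers of the control side. Other seed sites were not excluded. Seed effects through other genes, a difference common to all 3 control libraries, or a shared effect of losing either protein stay open and were not tested.

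The G2/M list fell after siSIRT6 with a median of -0.89 (SD of the members 0.43). The tables argue against GC content and gene length (median -0.84 once that trend was removed) and against the deeper siSIRT6 library (-0.89 without siSIRT6 replicate 3, unrounded -0.8946). They also argue against the siSIRT6 heptamer family in the members' own 3' UTRs as the whole cause (-0.75 for the 21 members without it, 19 of them lower). That family leaves out related heptamers such as AACTTGT (z = -6.30 after siSIRT6 against control), and coding regions were not searched. Direct matches outside the family are therefore not excluded. Over the alternatives the median was -0.92 to -0.72 with adjusted p from 8.55e-19 to 0.0924, the highest with an estimated correlation. Loss of SIRT6, and a seed effect of its siRNA through other sites or other genes, stay open and may act together.

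There are 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. In each comparison 1 of the 10, the real one, reached its own count. The real counts and the highest of the other splits were 8194 and 0 after siSIRT6, 8308 and 4 after siKDM5C, and 6442 and 1 between the knockdowns. Every other split mixes the groups compared, so their difference adds to the spread within groups and low counts follow. The counts of the other splits are therefore no measure of chance.

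Antisense genes followed the genes they overlap. Across 1356 antisense genes that overlap 1 coding gene, Pearson's r of the log2 fold changes was 0.809 after siSIRT6 and 0.822 after siKDM5C, against 0.050 and 0.093 with the nearest coding gene that does not overlap. Values of overlapping genes are therefore less certain.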
